A study of Mus musculus with 4 samples.

How the data were processed

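Retinas of male C57BL/6J mice 8 weeks old were analysed after 5 daily injections of streptozotocin at 60 mg/kg per day or of citrate buffer, per the labels' protocols. Mice whose fasting glucose exceeded 250 mg/dL counted as diabetic, and retinas were taken 5 or 15 days into diabetes. Each of the 4 libraries pooled 3 mice. The retinas were freed of pigment epithelium, fixed for 24 h, dissociated for 20 min, passed through a 40 µm strainer and hybridised with mouse whole-transcriptome probes, and 4000 to 10000 cells per condition were captured on the Chromium X instrument of 10x Genomics. Probe-based profiling counts molecules of the targeted genes alone, 19059 here; the set held no probe for Sag, 4 further marker genes or the ribosomal protein genes, so that the ribosomal list gave no value. Cell Ranger 7.0.1 made the deposited UMI counts per gene and cell, per the file headers and the submitters' processing notes, which name GRCm38 and mm10 as builds; cells had already been called, the lowest deposited cell holding 499 UMIs. Whether the deposited counts were corrected for free RNA or doublets is not given in the sources used here.

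Cells with at least 500 UMIs, at least 250 genes and under 20% mitochondrial UMIs were kept. Doublets were scored per library with Scrublet in scanpy 1.11.5. The rule fixed before the data were examined was Scrublet's automatic threshold or, where that marked under 0.5% of cells, the highest scores up to 0.8% per 1000 cells. It left the control library of day 5 on the automatic threshold (54 cells) and the others on the highest scores (271, 157 and 141 cells for the control library of day 15 and the diabetic libraries of days 5 and 15), an uneven treatment. In all 22970 of 23901 cells were kept. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9) gave 28 clusters over all libraries with no integration. Clusters were named from marker genes fixed in advance; clusters with fewer than 3 detected markers, mixed or contradicting leading genes, or a median UMI count far below that of their library and no marker among the leading 10 genes stayed unnamed, and so did clusters with a mean doublet score over 0.1, a limit chosen after the data were seen. Classes with at least 50 cells in each library were compared; class names are rebuilt from markers and written with the ending -like. Cluster 6 was the largest rod-like cluster, cluster 7 the largest amacrine-like cluster and cluster 13 the largest cone bipolar-like cluster in every library, and each other class compared was 1 cluster.

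UMIs were summed per library and class and divided by the class total (CPM). A gene was compared in a class with at least 100 UMIs over the 4 libraries, a mean CPM of at least 20, and at least 20% of its mean CPM in the class where it was highest, a limit meant against free RNA, which it does not remove. The log2 ratio of CPM has an exact conditional binomial (Clopper-Pearson) interval at 95%; shares have exact binomial intervals and levels exact Poisson intervals. These cover counting error only. A count of 0 was set to a floor of 3 counts per library. A gene is called apart at 1.5-fold or more with an interval that leaves out 1, a rule of size. No test was run, since each group is 1 library. A model of diabetes and day over the 4 libraries, which would leave 1 residual degree of freedom, was not fitted. Pearson and Spearman correlations across genes compare the 2 diabetes ratios, which share no library; the control pair shares a library with each and was not correlated with them. Named genes follow a rule fixed before the data were examined: up to 8 genes higher and 8 lower at both days in rod-like and Müller glia-like cells, and up to 4 and 4 in the other classes, with ratios above that of the control pair; the 4 highest and 4 lowest at each day in the first 2 classes; 2 to 4 members of each list described; and Rho, Opn1sw, Glul, Gfap, Vegfa, Txnip, Pink1, Bnip3, Hk2, Per2 and Dbp where compared. The 33 gene lists were fixed in advance, and a list's median was placed among 10000 random lists of its size matched on mean CPM in 20 bins. Lists with at least 5 compared genes are described where their median lay outside the central 95% at both days, or at 1 day in rod-like or Müller glia-like cells; this rule and the minimum of 5 were set after the data were seen. Gene positions came from GENCODE vM21 on GRCm38.

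The comparison was tested on simulated counts drawn from the class means of these libraries, with 200 genes changed. In Müller glia-like cells, of 8025 simulated genes, 91.7% of those changed 2-fold and 47.0% of those changed 1.5-fold were called apart, and in rod-like cells, of 7090, 100% and 48.3%. Class totals ran from 1156034 UMIs (Müller glia-like, diabetic, day 5) to 18741993 (rod-like, control, day 5), so that ratios are most precise in rod-like cells. Each result was recomputed under 14 alternatives fixed in advance (cells, doublets, scaling with edgeR 4.0.16 TMM and DESeq2 1.42.0 median-of-ratios factors, thinning, cell weights, gene limits, rod genes, clustering resolution and fold) and 4 chosen after the data were seen, the last of which leaves out cells of the cone cluster with more rod than cone marker UMIs (cells rich in rod RNA). Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and R 4.3.3 were used.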

Results

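Retinas of male C57BL/6J mice, an inbred laboratory strain, were profiled by probe-based single-cell RNA sequencing of fixed cells after injection of streptozotocin, a toxin of pancreatic beta cells that makes mice diabetic, or of citrate buffer. The 4 groups formed a 2 by 2 layout of diabetes and time, buffer and diabetic mice at 5 and 15 days of hyperglycaemia. Each group was 1 library made from the pooled retinas of 3 mice. The study title speaks of a transcriptional program of diabetes that precedes retinopathy, and the layout asks which retinal genes differ between diabetic and control retina at each day. The deposited matrices held 9241 cells for the control library of day 5, 5920 for the control library of day 15, 4490 for the diabetic library of day 5 and 4250 for the diabetic library of day 15. Their total counts were 63815319, 49069029, 38686879 and 38862474 unique molecular identifiers (UMIs). The unit CPM is a gene's UMI count scaled to the UMI total of its cell class. Median UMIs per cell were 2662, 4280.5, 4327.5 and 4944.5. With 1 library per group no difference had a replicate check, no test was run, and the intervals given with log2 ratios of CPM and with shares cover counting error at 95% and nothing else. Gene positions are those of GENCODE vM21 on GRCm38.

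Rod-like cells, the photoreceptors of dim light, made up 50.6% (49.6 to 51.7) of kept cells in the control library and 66.5% (65.1 to 68.0) in the diabetic library at day 5. At day 15 they made up 68.7% (67.4 to 69.9) in the control and 65.0% (63.5 to 66.5) in the diabetic library. The day 5 control library also held most of cluster 2, a cluster without a class name and with a median of 1078 UMIs per cell: 1673 of its 1721 cells came from that library. Müller glia-like cells, the main glia of the retina, were 2.78% (2.45 to 3.14) and 2.83% (2.35 to 3.37) at day 5 in the control and the diabetic library, and 2.98% (2.54 to 3.46) and 3.82% (3.25 to 4.46) at day 15. Amacrine-like cells, inhibitory interneurons, were 5.86% (5.39 to 6.36) and 6.52% (5.80 to 7.31) at day 5, and 6.87% (6.22 to 7.57) and 9.15% (8.28 to 10.1) at day 15. Cone-like cells were 3.94% (3.55 to 4.36) and 5.12% (4.48 to 5.82) at day 5, and 4.31% (3.79 to 4.88) and 3.75% (3.18 to 4.38) at day 15. Without cells that held more rod than cone marker UMIs, cone-like cells were 2.55% and 3.53% at day 5. Retinal ganglion-like cells were 1.07% (0.866 to 1.30) and 1.43% (1.09 to 1.83) at day 5, and 1.01% (0.764 to 1.31) and 1.5% (1.15 to 1.93) at day 15. With all deposited cells they were 3.42% and 4.12% at day 5 and 4.83% and 4.59% at day 15, where the direction turned. Rod bipolar-like cells were 2.24% (1.95 to 2.57) and 3.39% (2.87 to 3.98) at day 5, and 3.77% (3.28 to 4.30) and 3.77% (3.21 to 4.41) at day 15. Cone bipolar-like cells were 5.64% (5.18 to 6.14) and 6.80% (6.07 to 7.60) at day 5, and 6.04% (5.43 to 6.70) and 6.73% (5.98 to 7.55) at day 15. Microglia-like and horizontal-like cells were too few to compare, from 3 to 16 and from 9 to 28 cells per library. A limit on the doublet score, set after the data were seen, kept cluster 9 (rod bipolar markers) and cluster 22 (Müller glia markers) out of their classes. Cluster 9 held 1.35% of kept cells in the control library of day 5, 0.444% in the diabetic library of day 5, 0.0902% in the control library of day 15 and 0.345% in the diabetic library of day 15. In the same order cluster 22 held 1.24%, 0.351%, 0.126% and 0.197%. With these clusters named, the day 5 shares in the control and diabetic libraries were 3.60% and 3.83% for rod bipolar-like and 4.03% and 3.18% for Müller glia-like cells. At Leiden resolution 0.5 they were 3.37% and 3.83%, and 3.50% and 2.92%. With doublets kept, Müller glia-like cells were 1.65% and 2.39% at day 5. Unnamed cells count in the total of each library. They were 27.3% (26.4 to 28.3) and 6.97% (6.22 to 7.77) at day 5 in the control and the diabetic library, and 5.97% and 5.97% at day 15. This lowers every class share of the day 5 control library, so day 5 directions can depend on it. Shares among named cells alone were not computed. At day 5 the control and diabetic libraries held 4604 and 2846 rod-like cells. They held 253 and 121 Müller glia-like, 533 and 279 amacrine-like and 513 and 291 cone bipolar-like cells. Relative to rod-like cells these classes were fewer in the diabetic library, against the direction of their shares above. Rod bipolar-like (204 and 145) and retinal ganglion-like cells (97 and 61) stayed higher, and cone-like cells (358 and 219) were near even. Capture, dissociation and the doublet treatment can set these shares and counts. The last left out 0.590% of cells in the control library of day 5 and 4.66%, 3.54% and 3.36% in the control library of day 15 and the diabetic libraries of days 5 and 15.

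A gene is called apart between libraries at a ratio of at least 1.5-fold with a counting interval that leaves out a ratio of 1. The number of genes apart between diabetic and control libraries was smallest in rod-like and amacrine-like cells and largest in Müller glia-like cells at day 5 and cone-like cells at day 15. At day 5 the genes apart numbered 29 of 7121 in rod-like, 156 of 7146 in cone-like and 385 of 7165 in rod bipolar-like cells. They numbered 151 of 8074 in cone bipolar-like, 561 of 8054 in Müller glia-like, 57 of 8240 in amacrine-like and 123 of 7936 in retinal ganglion-like cells. At day 15 they numbered, in the same order, 13, 344, 163, 63, 292, 22 and 229. Müller glia-like cells were the largest at day 5 under all 18 alternatives, and cone-like cells at day 15 under 13 of them. None of the alternatives made depth equal between classes, so the ranking of classes is not separated from depth. At day 15 Müller glia-like cells exceeded cone-like cells with doublets kept (295 against 165), without the 20% limit on genes (394 against 381) and without cone-like cells rich in rod RNA (289 against 284). With all deposited cells Müller glia-like and retinal ganglion-like cells had 227 each against 193, and with cells weighted equally retinal ganglion-like cells had 420 against 259. Rod-like and amacrine-like cells were the smallest except with 2-fold as the size at day 5 (cone-like 6, amacrine-like 9) and at a mean CPM of at least 100 at day 15 (cone bipolar-like 2, rod-like 4). The 2 control libraries, which differ in day, mice and preparation and not in diabetes, were 7, 287, 181, 58, 269, 32 and 182 genes apart, a yardstick for how far libraries without diabetes differ. The diabetes comparison exceeded it by more than 1.5 times at day 5 in rod-like, rod bipolar-like, cone bipolar-like, Müller glia-like and amacrine-like cells, and at day 15 in rod-like cells. At day 5 that held under 17 of 18 alternatives in rod-like cells, 16 each in rod bipolar-like, cone bipolar-like and Müller glia-like cells and 8 in amacrine-like cells, and at day 15 under 17 in rod-like cells. With the doublet-score clusters named, the control pair exceeded the day 5 comparison in Müller glia-like cells, 1003 genes against 558. At day 15 the other 6 classes were within 1.5 times of the yardstick. In rod bipolar-like and amacrine-like cells the day 15 count was below the yardstick, as under 18 of 18 alternatives. In retinal ganglion-like cells the day 5 count was below it, as under 15 of the 16 alternatives that gave a value. The day 15 comparison lay more than 1.5 times below it under 4 alternatives in rod bipolar-like, 2 in cone bipolar-like, 2 in Müller glia-like and 6 in amacrine-like cells, and more than 1.5 times above it under 1 in cone-like, 2 in cone bipolar-like and 1 in retinal ganglion-like cells. At day 5 cone-like cells lay below it by more than 1.5 times, as under 14 of 18 alternatives, but above it without cells rich in rod RNA, 410 against 204. The 2 diabetic libraries were 23, 1142, 259, 109, 445, 43 and 241 genes apart. That pair also exceeded the yardstick by more than 1.5 times, in rod-like, cone-like, cone bipolar-like and Müller glia-like cells. Such an excess is thus not particular to diabetes against control. The diabetic library of day 5 enters both this pair and the day 5 comparison. Counting noise alone, in genes simulated with no change, put 110 genes apart in Müller glia-like cells at day 5 and 0 in rod-like cells. These classes had 1156034 to 2176324 and 12580686 to 18741993 UMIs per library. Between the control libraries noise put 68 and 0 apart in these classes, and in rod bipolar-like cells 61 at day 5 and 33 between the controls. Noise was thus itself larger at day 5 in Müller glia-like and rod bipolar-like cells, and is part of their margin over the yardstick.

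**Figure D1:**
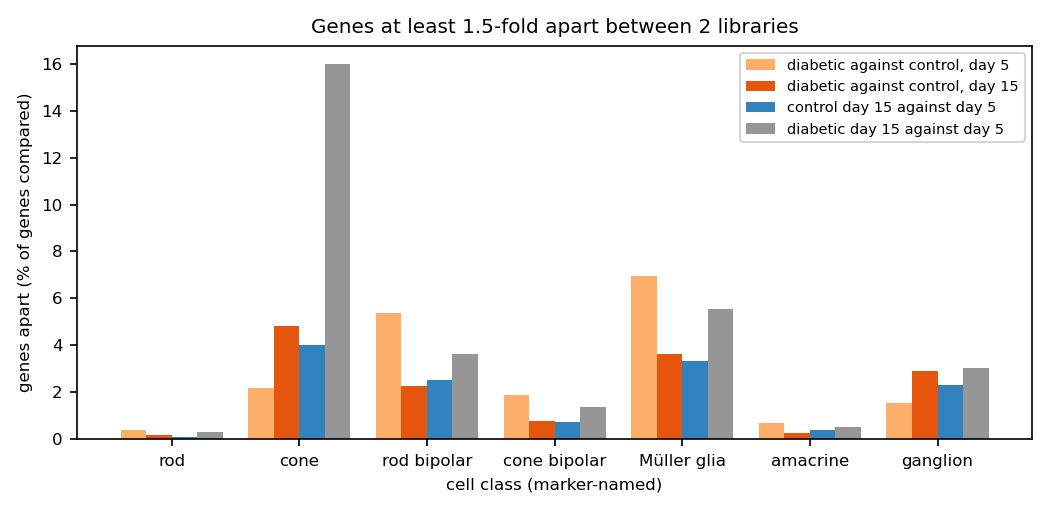
Genes at least 1.5-fold apart between 2 libraries, in percent of the genes compared in each marker-named cell class, with 1 bar per pair of libraries. The highest bar is the pair of diabetic libraries in cone-like cells, 16.0%, and the control pair lies at 3.34% in Müller glia-like and 0.0983% in rod-like cells.

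In rod-like cells, Selenbp1, which encodes a selenium-binding methanethiol oxidase, and the replication-dependent histone genes Hist1h1e and Hist2h4 were higher in the diabetic library at both days. Selenbp1 (chromosome 3, 94933056 to 94944758) was at 34.7, 65.4, 23.7 and 44.2 CPM in the day 5 control, day 5 diabetic, day 15 control and day 15 diabetic libraries. Its log2 ratio was 0.91 (0.76 to 1.06) at day 5 and 0.90 (0.71 to 1.09) at day 15, against -0.55 between the control libraries. Hist1h1e (chromosome 13, 23620629 to 23622558), a linker histone, had log2 ratios of 0.71 (0.64 to 0.79) and 0.95 (0.88 to 1.02). Hist2h4 (chromosome 3, 96261682 to 96263311) had 0.75 (0.62 to 0.89) and 0.73 (0.62 to 0.84), with 0.69 between the controls. At day 15, Arrdc3 (chromosome 13, 80883384 to 80896042), an arrestin-domain gene, had a log2 ratio of 1.22 (1.14 to 1.30), with 127 CPM in the control and 295 in the diabetic library. The histone genes Hist4h4 at 1.08, H1f0 at 0.72 and Hist1h2bc at 0.70 were higher as well. All 3 were below the 1.5-fold size at day 5 (0.50, 0.35 and 0.55). Counts of near-identical histone genes can be divided differently by probes, so single histone genes are uncertain. Genes lower at day 5 were led by the linker histone gene H1foo, -2.08 (-2.30 to -1.87) with -0.92 between the controls, the actin regulator Eps8l1, -1.44 (-1.65 to -1.24), the amino acid transporter gene Slc43a2, -0.84, and Hapln3, -0.83. H1foo was also lower at day 15, at -0.70 (-0.91 to -0.49), where Ptpn20 (-0.81) and Trib1 (-0.60) were also lower. Ptpn20 no longer met the limits for a comparison without the highest cell of each library. Abhd14b (0.71), the mitochondrial folate enzyme gene Mthfd2 (0.65, with 0.87 between the controls) and Fcer1g (0.65) were the other genes among the highest at day 5. Of the genes apart, 6 were higher and 23 lower at day 5 and 10 and 3 at day 15; the day 5 split was 11 higher and 12 lower with TMM factors, and 12 and 12 with median-of-ratios factors. Across genes the log2 ratios of the 2 days had a Pearson r of 0.458 and a Spearman rho of 0.412, genes not being independent replicates. In all, 4 genes were apart the same way on both days (3 higher, 1 lower) where independent lists would give 0.00843 and 0.00969. Rhodopsin (Rho) was at 0.06 and 0.06.

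In Müller glia-like cells, 11 genes were higher and 16 lower in the diabetic library on both days, where independent lists would give 3.60 and 6.23. Another 17 were apart in opposite ways on the 2 days, for which the number from independent lists was not worked out. Txnip (chromosome 3, 96557957 to 96561883), the glucose-inducible inhibitor of thioredoxin, was at 124, 234, 165 and 258 CPM in the day 5 control, day 5 diabetic, day 15 control and day 15 diabetic libraries. Its log2 ratios were 0.92 (0.67 to 1.17) and 0.64 (0.43 to 0.86), with 0.42 between the controls. The insulin-like growth factor binding protein gene Igfbp5 was higher by 0.91 (0.36 to 1.47) and 0.75 (0.25 to 1.26), and the metalloproteinase gene Mmp16 by 0.77 and 0.88. L3hypdh (1.23 and 1.21), the ciliary gene Cfap54 (0.94 and 0.94), the desmosomal cadherin gene Dsc2 (0.83 and 0.81), Lrrn2 (0.74 and 0.67) and Krcc1 (0.65 and 0.63) were the others of the 8 named under the fixed rule. Without the highest cell of each library L3hypdh no longer met the limits for a comparison. Lower on both days were Nampt, the rate-limiting enzyme of NAD salvage, at -0.67 (-1.28 to -0.10) and -0.97 (-1.59 to -0.38), and the Myc-family repressor gene Mnt (-0.86 and -0.86). So were the Egr corepressor gene Nab2 (-0.71 and -0.72), Wdr18 (-1.34 and -0.72), Zbtb49 (-0.74 and -0.68) and the fibrillin gene Fbn1 (-1.21 and -0.89, the second -0.37 without the highest cell of each library). Penk and Fbln1 also passed the size rule, but single cells carried them: 102 of 106 and 248 of 252 Penk UMIs of the control libraries were in 1 cell each, and so were all 55 and 128 Fbln1 UMIs. Of the genes apart at day 5, 181 were higher and 380 lower, a split of 262 higher and 266 lower with TMM factors, and 277 and 243 with median-of-ratios factors; at day 15 they were 160 higher and 132 lower, and 145 and 148 with TMM factors. The Pearson r across genes between the 2 days was 0.113.

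Interferon-responsive and antigen presentation genes were higher in the Müller glia-like cells of the diabetic library at day 5. Of 18 members of the list compared, 16 were above 0 at day 5 and 9 apart higher against 1 apart lower. The list median was 0.57, at percentile 100 of random lists matched on expression. Bst2 (tetherin, an antiviral membrane protein; chromosome 8, 71534255 to 71537456) had a log2 ratio of 1.98 (1.49 to 2.48), Ifit1 1.68 (1.05 to 2.34), Ifit3 1.32 (1.01 to 1.63) and Oasl2 1.25 (0.93 to 1.58). At day 15 the median was -0.10, with Bst2 at -0.46, Ifit1 at -0.11, Ifit3 at 0.03 and Oasl2 at 0.51. Without the highest cell of each library Bst2 turned to 0.05 and Oasl2 was apart at 0.68 at that day. The control libraries themselves differed by a median of 0.24 and by 1.26 for Bst2. Ly6e (1.76) and Gsn (1.38) were the other genes among the 4 highest at day 5, and at Leiden resolution 0.5 Ly6e turned to -0.19. Slc43a2 (-2.09), Crppa (-1.91), Trim68 (-1.70) and Zfp276 (-1.69) were the lowest at day 5 apart from genes lower on both days, and none of these 4 was apart at day 15. At day 15 Cyp26a1 (the retinoic acid hydroxylase; chromosome 19, 37697798 to 37701536) was at 1.48 (0.98 to 1.99), with 0.59 at day 5, where it was also apart, and -0.55 between the controls, Fam98c at 1.31, Arrdc3 at 1.26 (1.05 to 1.48) and the zinc transporter gene Slc39a8 at 1.12. Cdh23 (-1.34), Lhx9 (-1.30), Aif1l (-1.16) and Gorasp1 (-1.12) were the lowest at that day, again apart from genes lower on both days. The metallothionein genes of the glucocorticoid response list, metal-binding proteins induced by zinc and glucocorticoids, were lower at both days. Mt2 was at -1.30 (-1.46 to -1.15) and -0.55 (-0.66 to -0.44) and Mt1 at -0.71 and -0.33, and only the day 5 values reached 1.5-fold. Immediate early genes had a median of 0.08 at day 5 and 0.49 at day 15, with 5 of 6 members above 0 at day 15, Klf6 apart at 0.94 at day 15 and Jun at 0.54, short of 1.5-fold. The unfolded protein and integrated stress response list had a median of 0.00 and -0.18. Its members with the largest mean ratios were Sesn2 (-0.15 and -1.0), Atf5 (-0.45 and -0.36), Atf4 (-0.49 and -0.31) and Ddit3 (-0.45 and -0.27). They were picked by size, and Atf5, Atf4 and Ddit3 lay further below 0 at day 5, so they do not show the lower day 15 median. Without the highest cell of each library, Ifit1, Ly6e, Crppa, Trim68, Cdh23, Lhx9, Slc39a8 and Sesn2 no longer met the limits for a comparison. Gfap, the marker of reactive glia, had 1, 3, 0 and 26 UMIs in the class and was not compared, and glutamine synthetase (Glul) was at 0.19 and 0.06. Rho, a transcript of rods, was at 2481, 641, 149.97 and 702 CPM in these cells in the same order of libraries.

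**Figure D2:**
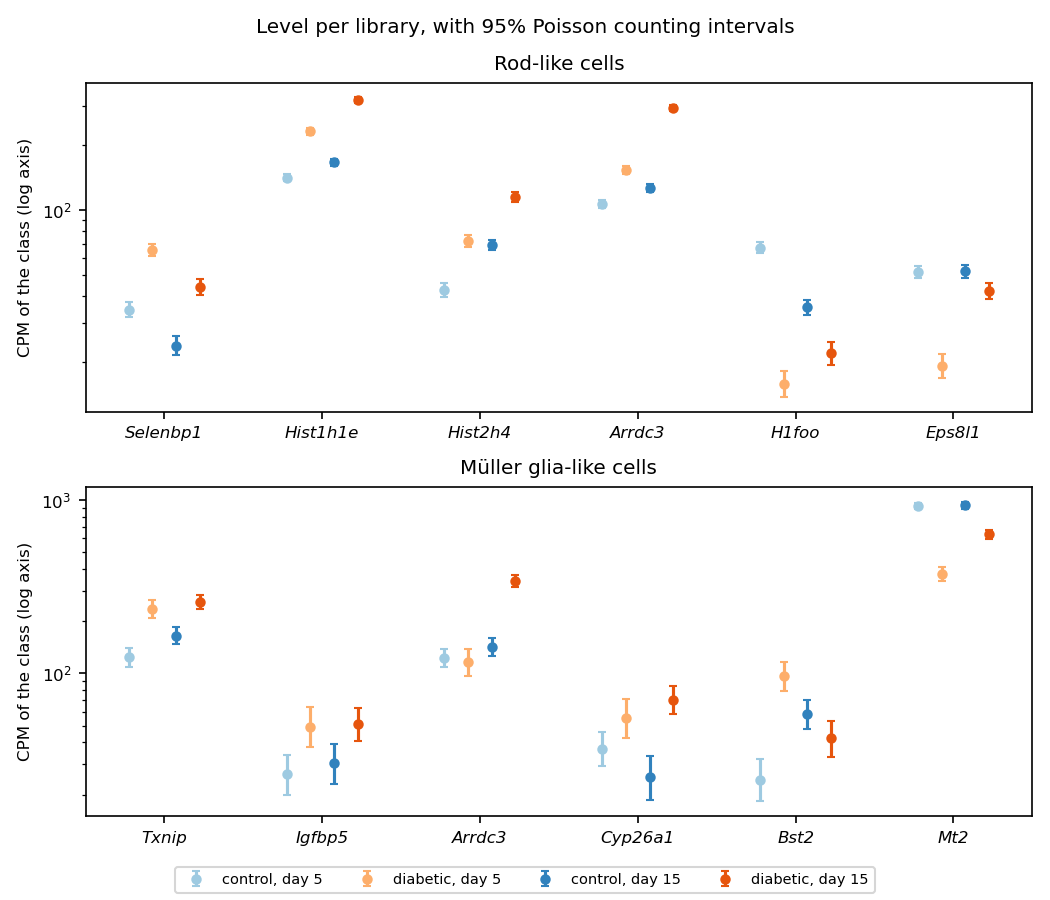
Level of named genes in rod-like and Müller glia-like cells, in CPM of the class on a log axis, with 1 point per library and its 95% Poisson counting interval. Selenbp1 in rod-like cells lies at 65.4 and 44.2 CPM in the diabetic and 34.7 and 23.7 in the control libraries of days 5 and 15, and Txnip in Müller glia-like cells at 234 and 258 against 124 and 165.

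The hypoxia response list holds targets and regulators of hypoxia-inducible factor. Its median log2 ratio was below 0 in 6 of 7 classes at day 5 and in 7 of 7 at day 15, and below 0 in 1 class between the control libraries. It lay below the central 95% of random lists in 4 classes at day 5 and 5 at day 15, on both days in rod bipolar-like and amacrine-like cells. Within that range were rod-like, Müller glia-like and cone-like cells at day 5, at percentiles 3.01, 11.5 and 96.3, and cone bipolar-like and retinal ganglion-like cells at day 15, at 5.04 and 2.77. Over the 86 pairs of member and class, 17 were apart lower and 0 higher at day 5, and 1 lower and 1 higher at day 15. In rod bipolar-like cells the list median was -0.37 at day 5 and -0.21 at day 15, with -0.08 between the control libraries, 12 and 11 of 13 members lying below 0. Ankrd37 was there at -0.81 (-1.05 to -0.58) and -0.41 (-0.63 to -0.19), the glycolytic regulator gene Pfkfb3 at -0.85 and -0.24, the mitophagy receptor gene Bnip3 at -0.52 and -0.46 and Ddit4, an inhibitor of mTORC1, at -0.88 and -0.08. In amacrine-like cells it was -0.32 at day 5 and -0.11 at day 15, with 0.10 between the control libraries. Pfkfb3 was there at -1.05 (-1.31 to -0.80) and -0.26 (-0.45 to -0.08), Ankrd37 at -0.77 and 0.01 and Kdm3a at -0.66 and -0.09. In rod-like cells it was -0.12 at day 5 and -0.18 at day 15, with 0.07 between the control libraries, with Ddit4 at -0.54 and -0.34 and no member apart. In Müller glia-like cells it was -0.09 at day 5 and -0.25 at day 15, with 0.07 between the control libraries. Vegfa (chromosome 17, 46016993 to 46032369), the vascular growth factor gene, was at -1.12 (-1.50 to -0.75) and -0.31 (-0.56 to -0.06) and Kdm3a at -0.64 and -0.15. Cone bipolar-like cells had medians of -0.55 and -0.08, retinal ganglion-like cells -0.24 and -0.11, and cone-like cells 0.05 and -0.18. In cone-like cells Vegfa was higher at day 15, at 0.70 (0.46 to 0.95), with 0.16 at day 5 and 0.77 between the controls. Without cone-like cells rich in rod RNA it was at 0.51 and 0.48, short of 1.5-fold. Vegfa was also at -0.59 and 0.13 in cone bipolar-like, -0.40 and -0.18 in amacrine-like, -0.44 and -0.15 in retinal ganglion-like and -0.01 and -0.14 in rod bipolar-like cells. Bnip3 was at -0.61 and -0.14 in cone bipolar-like, -0.27 and -0.07 in amacrine-like and -0.10 and 0.23 in retinal ganglion-like cells, apart in the first of these at day 5. The list of glycolysis genes in amacrine-like cells, which shares Pfkfb3, had medians of -0.05 and -0.06.

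**Figure D3:**
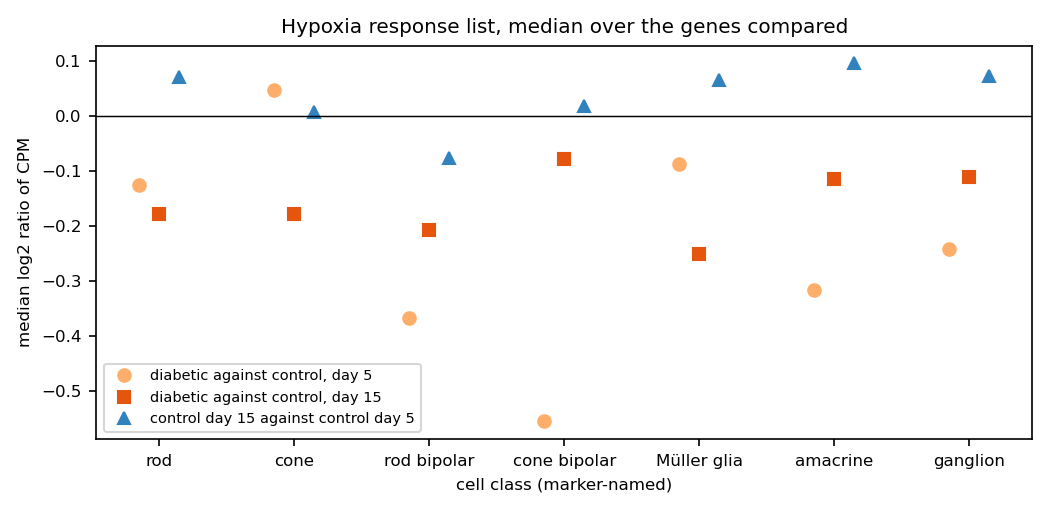
Median log2 ratio of CPM over the compared members of the hypoxia response list, by marker-named cell class, for the diabetic against the control library at each day and for the 2 control libraries. The day 15 medians lie from -0.25 to -0.08 and the medians between the controls from -0.08 to 0.10.

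In cone-like cells, the immediate early genes were higher in the diabetic library at both days, led by Egr1 (chromosome 18, 34859823 to 34864984), an activity-induced transcription factor, at 1.14 (0.47 to 1.83) and 4.25 (3.50 to 5.09). At day 15 Egr1 UMIs were in 42 diabetic cells, the highest with 32 of 148. The list median was 0.27 at day 5 and 0.38 at day 15, with 0.21 between the control libraries, with 6 and 6 of 7 members above 0 and 1 and 3 apart higher. Egr3 at day 15 was 2.39 and Nr4a1 1.28. The mitochondrial phenylalanine-tRNA synthetase gene Fars2 (0.73 and 0.75), Tc2n (0.83 and 1.14) and Inhbb (1.08 and 1.10, with 1.08 between the controls) were higher on both days. Eps8l1 (-1.26 and -1.19), Taf7 (-0.64 and -0.81) and Zfp46 (-0.65 and -0.84) were lower. Zfp46 at day 5 turned to 0.13 with cells weighted equally. Egr3, Eps8l1 and Zfp46 no longer met the limits for a comparison without the highest cell of each library. Kif4 was at -1.34 and -0.64, and is itself among the genes that define this cluster. Rod phototransduction genes were on opposite sides at the 2 days, with a median of 0.21 at day 5 and -0.74 at day 15 and -0.34 between the controls; 12 of 22 members were apart lower at day 15. Gnat1 was at 0.27 and -1.24, Cnga1 at 0.22 and -1.19, Gnb1 at 0.04 and -1.17 and Rho at 0.24 and -1.30. With cells weighted equally the day 5 median turned to -0.02, Rho to -0.10 and Cnga1 to -0.15. Rho stood at 45052, 53131, 34171 and 13858 CPM in the cone-like cells of the day 5 control, day 5 diabetic, day 15 control and day 15 diabetic libraries, a level near that in rod-like cells in the first 3 of them. Opn1sw, the short-wave opsin, was at 4685, 4485, 8660.1 and 9082 CPM in that order, so that the day 15 libraries lay above the day 5 libraries in either condition. In the same order, 35.2% (30.2 to 40.4), 31.1% (25 to 37.6), 11.3% (7.58 to 16.0) and 6.58% (3.20 to 11.8) of the cells held more rod than cone marker UMIs. Without these cells, a setting chosen after the data were seen, the rod phototransduction medians were -0.08 and -0.04 and the immediate early medians 0.35 and 0.38. Genes apart then numbered 410 at day 5 (127 higher, 283 lower) and 284 at day 15 (162 and 122). Fars2 and Taf7 at day 5 were then at 0.58 and -0.22 and Inhbb at day 15 at 0.55, each short of 1.5-fold, and Eps8l1 no longer met the limits for a comparison. Opn1sw was then at -0.14 and -0.22, where all cells gave -0.06 and 0.07. With all cone-like cells counted, 24 genes were apart higher and 132 lower at day 5, a split of 53 higher and 56 lower with TMM factors, and 57 and 53 with median-of-ratios factors. At day 15 they were 222 higher and 122 lower, a split of 142 higher and 193 lower with TMM factors, and 149 and 183 with median-of-ratios factors. At a mean CPM of at least 100 they were 3 and 1 at day 5 and 25 and 39 at day 15.

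In rod bipolar-like cells, the endoplasmic reticulum stress kinase gene Eif2ak3 (PERK) was higher in the diabetic library on both days, at 0.81 (0.37 to 1.26) and 0.86 (0.52 to 1.21). Phtf2 (1.04 and 0.96), Eva1c (1.44 and 0.93) and Uxs1 (0.71 and 0.85) were higher as well. The synaptic scaffold gene Baiap2 (-1.47 (-1.93 to -1.04) and -0.70), the peroxiredoxin gene Prdx4 (-1.18 and -0.70), Caap1 (-0.81 and -0.75) and the helicase gene Recql (-0.65 and -0.69) were lower. Eva1c and Caap1 no longer met the limits for a comparison without the highest cell of each library. Genes apart were 172 higher and 213 lower at day 5, turning to 25 and 16 at a mean CPM of at least 100 and 226 and 219 with cells weighted equally, and 119 and 44 at day 15. Cone bipolar-like cells had Hist1h1e (0.60 (0.45 to 0.74) and 0.71 (0.57 to 0.84)), the growth factor feedback inhibitor gene Spry4 (0.79 and 0.63), the mitochondrial folate enzyme gene Aldh1l2 (0.62 and 0.65) and Tshz2 (0.61 and 1.05) higher on both days. Without the highest cell of each library Hist1h1e was at 0.58 at day 5, short of 1.5-fold, and Tshz2 no longer met the limits for a comparison. The cyclin gene Ccng2, a target of FOXO factors, was lower (-0.82 (-1.07 to -0.58) and -0.62 (-0.84 to -0.41)). Genes apart there were 62 higher and 89 lower at day 5, a split of 75 and 71 with TMM factors, and 40 and 23 at day 15. No gene was apart the same way on both days in amacrine-like cells and 3 were apart in opposite ways, with 34 higher and 23 lower at day 5 and 15 and 7 at day 15; without the 20% limit on genes the day 5 split turned to 38 higher and 72 lower.

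In retinal ganglion-like cells, the muscarinic receptor gene Chrm2 (2.36 (1.85 to 2.90) and 1.23 (0.52 to 1.97)), Kctd4 (1.45 and 2.26), the titin gene Ttn (1.27 and 2.26) and the transcription factor gene Mafb (1.2 and 1.49) were higher in the diabetic library on both days. The nicotinic receptor gene Chrna4 (-0.60 and -0.61) and the growth factor gene Tgfb3 (-0.84 and -0.59) were lower. Few cells carried them: Ttn UMIs were in 5 to 12 cells per library, and 44 of 153 Chrm2 UMIs of the day 5 diabetic library in 1. With cells weighted equally, the day 15 log2 ratios of Mafb, Chrna4 and Tgfb3 turned to -0.80, 0.75 and 0.37. Genes apart were 63 higher and 60 lower at day 5 and 127 and 102 at day 15. With cells weighted equally they were 120 and 144 at day 5. Without each gene's highest cell they were 43 and 75 at day 5 and 149 and 62 at day 15, and without the 20% limit on genes 149 and 196 at day 15. Cholesterol synthesis genes had a median of 0.29 at day 5 and -0.11 at day 15, with Ldlr at 0.77 and 0.48 and Stard4 at 0.57 and 0.16, the first turning to -0.11 with cells weighted equally. The tricarboxylic acid cycle list had medians of -0.09 and -0.10 against 0.15 between the controls, turning at day 15 to 0.05 with cells weighted equally and 0.06 without each gene's highest cell. Of its members, Mdh1 was at -0.24 and -0.26, Ogdh at -0.09 and -0.21 and Suclg1 at 0.34 and -0.02. Without the highest cell of each library the day 15 ratio of Mdh1 turned to 0.03 and that of Ogdh was -0.04, and with cells weighted equally the day 5 ratio of Suclg1 turned to -0.02.

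Mitochondrially encoded transcripts were lower in the diabetic library at both days in rod-like, Müller glia-like and amacrine-like cells, and lower by more in list median between the control libraries. In rod-like cells the list median was -0.12 at day 5 and -0.22 at day 15, with -0.48 between the control libraries. For Müller glia-like cells it was -0.46 at day 5 and -0.25 at day 15, with -0.65 between the control libraries. In amacrine-like cells it was -0.05 at day 5 and -0.15 at day 15, with -0.43 between the control libraries. In retinal ganglion-like cells it was -0.08 at day 5 and -0.36 at day 15, with -0.38 between the control libraries, 12 and 13 of 13 members lying below 0. In rod bipolar-like cells it was 0.13 at day 5 and -0.04 at day 15, with -0.34 between the control libraries, with 13 of 13 members above 0 at day 5 and 3 at day 15. In cone-like cells it was 0.10 at day 5 and -0.09 at day 15, with -0.12 between the control libraries, with 11 and 2 members above 0, and in cone bipolar-like cells 6 and 3 of 13 were above 0. In rod-like cells mt-Nd4 was at -0.23 and -0.46 with -0.41 between the controls, and in Müller glia-like cells mt-Nd4 was at -0.97 and -0.44 with -0.67. The nuclear-encoded oxidative phosphorylation list in cone bipolar-like cells was at -0.08 at day 5 and 0.08 at day 15, and the inhibitory neurotransmission list in amacrine-like cells at 0.15 and -0.07. Circadian clock genes in rod-like cells had medians of -0.21 and -0.08 with -0.13 between the controls, led by Cry1 at -0.47 and -0.20; the hour of collection is not given in the sources used here. Immediate early genes in rod-like cells had medians of -0.20 and -0.16, with Ier3 at -0.29 and -0.28, in the opposite direction to cone-like cells, a difference that was not tested. The same list had a median of 0.29 at day 5 in amacrine-like cells, with 10 of 10 members above 0 and 4 apart higher, and 5 above 0 at day 15. It was at 0.10 and 0.39 in rod bipolar-like cells, with 6 of 6 above 0 and 2 apart higher at day 15, and at 0.05 and 0.12 in retinal ganglion-like cells. In cone bipolar-like cells it was at -0.28 and 0.25. Apoptosis genes in rod-like cells had medians of 0.00 and 0.06. No member of the mitochondrial list was apart between diabetic and control libraries in rod-like or amacrine-like cells. Between the 2 diabetic libraries 11 of 13 were apart lower at day 15 in rod-like, 10 in retinal ganglion-like and 1 in amacrine-like cells, and between the control libraries 1 in rod-like cells. Below 0 lay 12 and 13 of 13 in rod-like cells at days 5 and 15, and 3 of 7 were apart lower in Müller glia-like cells at day 5, against 5 between the control libraries. In cone bipolar-like cells 3 of 13 were apart lower between the control libraries and none between diabetic and control libraries. Over all 163 pairs of class and list, 32 medians at day 5 and 31 at day 15 lay outside the central 95% of random lists. So did 38 between the control libraries and 48 between the diabetic libraries, where chance gives 8.15 for each. On both days 9 lay outside on the same side, where chance gives 3.50, and 6 on opposite sides. The number that chance gives for opposite sides was not worked out, so the same-side excess alone does not measure agreement between days.

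Agreement between the 2 days was lower outside rod-like cells. These were also the deepest class, with 12580686 to 18741993 UMIs per library, and depth was not made equal between classes. The lower agreement elsewhere is thus not separated from depth. The Pearson r of the log2 ratios across genes was 0.0892, 0.121, 0.0454, 0.0766 and 0.0461 in cone-like, rod bipolar-like, cone bipolar-like, amacrine-like and retinal ganglion-like cells, and the Spearman rho 0.0599, 0.111, 0.00243, 0.128 and 0.0883. Genes apart higher on both days numbered 15 in cone-like, 10 in rod bipolar-like, 4 in cone bipolar-like and 10 in retinal ganglion-like cells, where independent lists would give 0.746, 2.86, 0.307 and 1.01. Genes apart lower on both days numbered 4, 6, 2 and 3 in these classes, where independent lists would give 2.25, 1.31, 0.254 and 0.771. Apart in opposite ways on the 2 days were 9, 4, 0 and 15 genes, in retinal ganglion-like cells more than the 13 apart the same way, and 0 in rod-like cells. The number that independent lists would give was not worked out for opposite ways, so the same-way excess alone does not measure agreement. Without each gene's highest cell in every library, 4 of 4 of the both-day genes stayed apart in rod-like, 14 of 19 in cone-like, 10 of 16 in rod bipolar-like and 3 of 6 in cone bipolar-like cells. The same held for 21 of 27 in Müller glia-like and 6 of 13 in retinal ganglion-like cells.

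Between the 2 diabetic libraries the genes apart were 880 higher and 262 lower at day 15 in cone-like cells, and 239 and 111 without the cells rich in rod RNA. There TMM factors gave 458 and 488 and median-of-ratios factors 461 and 486, the median log2 ratio of all genes there being 0.15. In Müller glia-like cells they were 307 higher and 138 lower (248 and 175 with TMM, 235 and 189 with median-of-ratios factors), and in rod-like cells 12 and 11 (6 and 15 with either set of factors). The interferon list in Müller glia-like cells had a median of -0.36 and the hypoxia response list in amacrine-like cells 0.27 from the day 5 to the day 15 diabetic library. Of genes chosen in advance for all classes, Pink1, a kinase that starts mitophagy, lay from -0.12 in Müller glia-like to 0.06 in cone-like cells at day 5 and from -0.21 in cone-like to 0.08 in amacrine-like cells at day 15, the cone-like value turning to 0.03 without the cells rich in rod RNA. The hexokinase gene Hk2 was at 0.18 (0.13 to 0.23) and 0.14 (0.09 to 0.18) in rod-like and 0.27 and 0.29 in cone-like cells, below 1.5-fold. The clock gene Per2 was apart higher in cone-like cells at both days, at 0.61 and 0.70 with 0.89 between the controls, and at 1.03 and 0.41 without the cells rich in rod RNA. It was apart lower at day 5 in retinal ganglion-like cells, at -0.66, with -0.17 at day 15. Elsewhere Per2 lay from -0.21 (cone bipolar-like) to 0.27 (rod bipolar-like) at day 5 and from -0.29 (rod bipolar-like) to 0.15 (Müller glia-like) at day 15. Dbp lay from -0.10 (Müller glia-like) to 0.30 (cone bipolar-like) at day 5 and from -0.17 (retinal ganglion-like) to 0.15 (cone-like) at day 15, with no class apart, and the last of these turned to -0.09 without the cells rich in rod RNA.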

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

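The tests of the cone-like pattern below were chosen after its values were seen, that of the rods of cluster 20 after the result for average rods. In 6 pairs of class and list the median lay outside the range of random lists on opposite sides at days 5 and 15; the difference between days was not tested, since each group is 1 library. The rod phototransduction list in cone-like cells was at 0.21 and -0.74, a difference of -0.95 on the log2 scale. The nuclear oxidative phosphorylation list in cone bipolar-like cells differed by 0.16 and the immediate early list there, at -0.28 and 0.25, by 0.54, with a control pair median of 0.19. At Leiden resolution 2.0 its day 5 median was 0.02, so that it no longer lay below 0. In Müller glia-like cells the glucocorticoid response list, at -0.12 and 0.18, differed by 0.30, and with the doublet-score clusters named the day 5 median was 0.04. Its members Klf9 and Zbtb16 were above 0 at both days (0.37 and 0.48, and 0.26 and 0.42). The inhibitory neurotransmission list in amacrine-like cells differed by -0.22, with Gad1 at 0.25 and 0.20 and Slc6a5 at -0.02 and -0.31, and the cholesterol synthesis list in retinal ganglion-like cells by -0.40.

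RNA of rods in the cells of the cone cluster is a candidate explanation for the rod phototransduction list there, whose rod markers summed to 78522, 92089, 57983 and 27419 CPM in the day 5 control, day 5 diabetic, day 15 control and day 15 diabetic libraries, against 74043 in rod-like cells and 179121 in cluster 20, the rod-like cluster richest in them. Average rods would have to supply 100% of the UMIs in both day 5 libraries, a ceiling, since rod markers there exceed those of rods. Day 5 thus could not test this source. In the day 15 control and diabetic libraries the shares would be 74.6% and 26.4%. That would put the 301 other genes at least 2-fold higher in rods at a median of -0.70 at day 15. The genes lay at -0.078 (-0.14 to -0.02 on resampling genes), which argues against average rods at these shares. RNA of rods like those of cluster 20 would put their 184 other genes at 0.12 at day 5 and -0.35 at day 15. These genes lay at 0.11 and -0.33 (-0.37 to -0.29 at day 15), so the values that this source needs are there. It would need 40.3%, 48.3%, 28.1% and 9.91% of the cone cluster's UMIs in the same order of libraries. Cluster 20 held 2.23%, 2.20%, 2.49% and 1.97% of kept cells. Its profile was chosen by the same markers that set the share, so the match does not single out these rods as the source. These predictions take the rod share of the UMIs from the rod markers and mix pooled profiles of the rods and of the cone-like cells with no more rod than cone marker UMIs. Whether diabetes changed the amount of such RNA cannot be told apart from the library with 1 library per group, and the list differed by -0.34 between the controls alone.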

How the results depend on the processing

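All groups share the single replicate number 1, so no pairing by replicate number was possible, and no result here comes from a test. A fit with day as a block, with 1 residual degree of freedom, could have been made and was not run. Among named log2 ratios, 5781 of 6026 recomputed values stayed within their counting interval and 143 changed sign, 5 of them of genes called apart. Among list medians described, 667 of 724 stayed within an interval set by the members' interquartile range over the root of their number. Of these recomputed medians 16 changed sign, 6 of them medians that lay outside the range of random lists. Of counts of genes apart, 379 of 496 stayed within 1.5 times, of counts on both days 97 of 124, of correlations between days 78 of 117 and of shares 252 of 320 within their interval. Given by setting are the counts, correlations and shares that did not, and the 5 ratios and 6 medians just named; the 240 further ratios and 51 further medians outside their interval are not listed. Of the settings, 4 (the highest Scrublet scores in all libraries, the doublet-score clusters named, each gene's highest cell left out, and cone cells with more rod than cone marker UMIs left out) were chosen after the data were seen; the cause was not tested, beyond the fewer or more genes or cells that a setting holds by construction. Retinal ganglion-like cells gave no value at 1000 UMIs or with the highest Scrublet scores left out in all libraries, since the class then held fewer than 50 cells in 1 library. No list median described at day 5 or 15 changed sign with TMM or median-of-ratios factors. Depth limits the small classes most, Müller glia-like and rod bipolar-like cells first.

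With at least 1000 UMIs per cell, a count of 101 genes in cone bipolar-like cells was apart at day 15. A count of 193 genes in cone bipolar-like cells was apart in the diabetic pair. An r of 0.121 in cone-like and 0.0809 in cone bipolar-like cells was found between days. Rod-like cells were 54.2% (control day 5). Cone-like cells were 4.42% (control day 5). Cone bipolar-like cells were 4.53% (control day 5), 4.99% (control day 15), 5.43% (diabetic day 5) and 5.21% (diabetic day 15). Amacrine-like cells were 7.62% (control day 5), 7.65% (control day 15) and 7.72% (diabetic day 5). Microglia-like cells were 0.0631% (control day 5). Unnamed cells were 22.3% (control day 5).

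With all deposited cells, a count of 193 genes in cone-like cells was apart at day 15. A count of 34 genes in cone bipolar-like and 156 in Müller glia-like cells was apart in the control pair. A count of 28 genes in amacrine-like cells was apart in the diabetic pair. An r of 0.176 in cone-like, 0.119 in cone bipolar-like, 0.195 in Müller glia-like and 0.118 in amacrine-like cells was found between days. Rod-like cells were 64.7% (control day 15), 63.4% (diabetic day 5) and 62.1% (diabetic day 15). Cone bipolar-like cells were 4.99% (control day 5) and 5.98% (diabetic day 15). Retinal ganglion-like cells were 3.42% (control day 5), 4.83% (control day 15), 4.12% (diabetic day 5) and 4.59% (diabetic day 15).

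With doublets kept, a count of 165 genes in cone-like cells was apart at day 15. A count of 29 genes in cone bipolar-like cells was apart in the control pair. A total of 1 genes in cone bipolar-like and 21 in retinal ganglion-like cells was apart on both days. An r of 0.187 in cone-like, 0.0998 in cone bipolar-like, 0.106 in amacrine-like and 0.0106 in retinal ganglion-like cells was found between days. Rod-like cells were 65.9% (control day 15), 64.2% (diabetic day 5) and 62.9% (diabetic day 15). Cone-like cells were 4.95% (control day 15). Müller glia-like cells were 1.65% (control day 5) and 3.15% (diabetic day 15). Amacrine-like cells were 6.75% (control day 5) and 7.75% (control day 15). Unnamed cells were 28.4% (control day 5), 7.77% (control day 15), 9.04% (diabetic day 5) and 8.46% (diabetic day 15).

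After thinning to the smallest total, a count of 304 genes in cone-like cells was apart at day 5. A count of 21 genes in rod-like cells was apart at day 15. A count of 99 genes in cone bipolar-like cells was apart in the control pair. A total of 7 genes in rod-like and 22 in retinal ganglion-like cells was apart on both days. An r of 0.0966 in rod bipolar-like cells was found between days.

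With cells weighted equally, a count of 44 genes in rod-like, 275 in cone-like, 105 in amacrine-like and 264 in retinal ganglion-like cells was apart at day 5. A count of 20 genes in rod-like, 58 in amacrine-like and 420 in retinal ganglion-like cells was apart at day 15. A count of 12 genes in rod-like, 77 in amacrine-like and 310 in retinal ganglion-like cells was apart in the control pair. A count of 459 genes in cone-like, 167 in cone bipolar-like, 88 in amacrine-like and 523 in retinal ganglion-like cells was apart in the diabetic pair. A total of 4 genes in amacrine-like cells was apart on both days. An r of 0.405 in rod-like, 0.0767 in rod bipolar-like, 0.0330 in amacrine-like and -0.00989 in retinal ganglion-like cells was found between days. The log2 ratio of Zfp46 in cone-like cells at day 5 turned from -0.65 to 0.13. The median of the rod phototransduction list in cone-like cells at day 5 turned from 0.21 to -0.0227. The log2 ratio of Mafb in retinal ganglion-like cells at day 15 turned from 1.49 to -0.80. The log2 ratio of Chrna4 in retinal ganglion-like cells at day 15 turned from -0.61 to 0.75. The log2 ratio of Tgfb3 in retinal ganglion-like cells at day 15 turned from -0.59 to 0.37. The median of the tricarboxylic acid cycle list in retinal ganglion-like cells at day 15 turned from -0.10 to 0.0527.

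At a mean CPM of at least 5, a count of 92 genes in rod-like, 307 in cone-like, 311 in cone bipolar-like, 209 in amacrine-like and 306 in retinal ganglion-like cells was apart at day 5. A count of 39 genes in rod-like, 165 in cone bipolar-like, 125 in amacrine-like and 432 in retinal ganglion-like cells was apart at day 15. A count of 24 genes in rod-like, 451 in cone-like, 191 in cone bipolar-like, 168 in amacrine-like and 365 in retinal ganglion-like cells was apart in the control pair. A count of 66 genes in rod-like, 255 in cone bipolar-like, 209 in amacrine-like and 455 in retinal ganglion-like cells was apart in the diabetic pair. A total of 8 genes in rod-like, 12 in cone bipolar-like, 10 in amacrine-like and 34 in retinal ganglion-like cells was apart on both days. An r of 0.438 in rod-like, 0.00853 in amacrine-like and 0.00507 in retinal ganglion-like cells was found between days.

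At a mean CPM of at least 100, a count of 1 genes in rod-like, 4 in cone-like, 41 in rod bipolar-like, 17 in cone bipolar-like, 46 in Müller glia-like, 2 in amacrine-like and 8 in retinal ganglion-like cells was apart at day 5. A count of 4 genes in rod-like, 64 in cone-like, 4 in rod bipolar-like, 2 in cone bipolar-like, 12 in Müller glia-like, 0 in amacrine-like and 24 in retinal ganglion-like cells was apart at day 15. A count of 1 genes in rod-like, 91 in cone-like, 16 in rod bipolar-like, 5 in cone bipolar-like, 14 in Müller glia-like, 3 in amacrine-like and 19 in retinal ganglion-like cells was apart in the control pair. A count of 13 genes in rod-like, 357 in cone-like, 14 in rod bipolar-like, 10 in cone bipolar-like, 37 in Müller glia-like, 6 in amacrine-like and 23 in retinal ganglion-like cells was apart in the diabetic pair. A total of 1 genes in rod-like, 2 in cone-like, 1 in rod bipolar-like, 1 in cone bipolar-like, 1 in Müller glia-like and 1 in retinal ganglion-like cells was apart on both days. An r of 0.545 in rod-like, -0.0211 in cone-like, 0.148 in rod bipolar-like, -0.0719 in cone bipolar-like and 0.121 in amacrine-like cells was found between days.

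Without the 20% limit on genes, a count of 110 genes in amacrine-like cells was apart at day 5. A count of 136 genes in cone bipolar-like, 35 in amacrine-like and 345 in retinal ganglion-like cells was apart at day 15. A count of 174 genes in cone bipolar-like, 502 in Müller glia-like and 174 in amacrine-like cells was apart in the control pair. A count of 116 genes in amacrine-like and 389 in retinal ganglion-like cells was apart in the diabetic pair. A total of 6 genes in amacrine-like cells was apart on both days. An r of -0.0239 in cone bipolar-like, -0.0757 in Müller glia-like and -0.0122 in retinal ganglion-like cells was found between days.

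At Leiden resolution 0.5, a count of 12 genes in rod-like, 348 in rod bipolar-like and 530 in Müller glia-like cells was apart in the control pair. A total of 46 genes in Müller glia-like and 1 in amacrine-like cells was apart on both days. An r of 0.0849 in rod bipolar-like, 0.0217 in cone bipolar-like and 0.188 in Müller glia-like cells was found between days. Rod bipolar-like cells were 3.37% (control day 5). Müller glia-like cells were 3.50% (control day 5). Unnamed cells were 24.6% (control day 5), 5.19% (control day 15), 5.38% (diabetic day 5) and 5.05% (diabetic day 15). The log2 ratio of Ly6e in Müller glia-like cells at day 5 turned from 1.76 to -0.19.

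At Leiden resolution 2.0, a count of 176 genes in cone bipolar-like cells was apart in the diabetic pair. A total of 1 genes in amacrine-like cells was apart on both days. An r of 0.110 in amacrine-like and 0.0176 in retinal ganglion-like cells was found between days. Cone bipolar-like cells were 4.70% (control day 5), 5.37% (control day 15), 5.66% (diabetic day 5) and 5.57% (diabetic day 15). Müller glia-like cells were 2.45% (control day 5). Unnamed cells were 29.3% (control day 5), 7.48% (control day 15), 9.19% (diabetic day 5) and 8.23% (diabetic day 15). The median of the immediate early list in cone bipolar-like cells at day 5 turned from -0.28 to 0.0206.

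With 2-fold as the size, a count of 2 genes in rod-like, 6 in cone-like, 45 in rod bipolar-like, 10 in cone bipolar-like, 74 in Müller glia-like, 9 in amacrine-like and 22 in retinal ganglion-like cells was apart at day 5. A count of 2 genes in rod-like, 53 in cone-like, 4 in rod bipolar-like, 4 in cone bipolar-like, 24 in Müller glia-like, 3 in amacrine-like and 34 in retinal ganglion-like cells was apart at day 15. A count of 0 genes in rod-like, 12 in cone-like, 15 in rod bipolar-like, 7 in cone bipolar-like, 16 in Müller glia-like, 7 in amacrine-like and 28 in retinal ganglion-like cells was apart in the control pair. A count of 1 genes in rod-like, 245 in cone-like, 29 in rod bipolar-like, 6 in cone bipolar-like, 72 in Müller glia-like, 6 in amacrine-like and 30 in retinal ganglion-like cells was apart in the diabetic pair. A total of 0 genes in rod-like, 3 in cone-like, 0 in rod bipolar-like, 0 in cone bipolar-like, 3 in Müller glia-like and 5 in retinal ganglion-like cells was apart on both days.

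With the highest Scrublet scores left out in all libraries, a count of 196 genes in cone bipolar-like cells was apart in the diabetic pair. A total of 3 genes in cone bipolar-like cells was apart on both days. An r of 0.204 in cone-like, 0.147 in rod bipolar-like and 0.0687 in cone bipolar-like cells was found between days. Rod-like cells were 53.2% (control day 5). Cone-like cells were 3.42% (control day 5). Rod bipolar-like cells were 2.57% (control day 5). Cone bipolar-like cells were 4.32% (control day 5), 5.27% (control day 15), 5.54% (diabetic day 5) and 5.40% (diabetic day 15). Amacrine-like cells were 6.95% (control day 5). Microglia-like cells were 0% (control day 5), 0% (control day 15), 0% (diabetic day 5) and 0% (diabetic day 15). Unnamed cells were 25.7% (control day 5).

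With the doublet-score clusters named, a count of 430 genes in rod bipolar-like and 1003 in Müller glia-like cells was apart in the control pair. An r of 0.0743 in rod bipolar-like and 0.00667 in Müller glia-like cells was found between days. Rod bipolar-like cells were 3.60% (control day 5). Müller glia-like cells were 4.03% (control day 5). Unnamed cells were 24.7% (control day 5) and 6.17% (diabetic day 5). The median of the glucocorticoid response list in Müller glia-like cells at day 5 turned from -0.12 to 0.0370.

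Without each gene's highest cell, a total of 1 genes in amacrine-like cells was apart on both days. An r of 0.120 in cone-like and 0.0888 in Müller glia-like cells was found between days. The median of the tricarboxylic acid cycle list in retinal ganglion-like cells at day 15 turned from -0.10 to 0.0595.

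Without cone-like cells rich in rod RNA, a count of 410 genes in cone-like cells was apart at day 5. A count of 350 genes in cone-like cells was apart in the diabetic pair. An r of 0.117 in cone-like cells was found between days. Cone-like cells were 2.55% (control day 5) and 3.53% (diabetic day 5). Unnamed cells were 28.7% (control day 5) and 8.56% (diabetic day 5). The median of the rod phototransduction list in cone-like cells at day 5 turned from 0.21 to -0.0799.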

Other observations

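The count of genes over classes, the tests of diabetes for both lists weighed here, the restriction of the test of a cluster mix to classes of several clusters, the reading of the free RNA test in which 1 day within its bound suffices, and the test of a low control library were chosen after the results were seen. At day 15 Arrdc3 was apart higher in 6 of the 6 classes where it was compared, with log2 ratios from 0.60 (amacrine-like) to 1.34 (cone-like), and from -0.34 to 0.52 at day 5. Hist1h1e was apart higher at day 15 in 5 of 7 classes, from 0.70 (retinal ganglion-like) to 0.95 (rod-like), with 0.58 in cone-like and 0.56 in amacrine-like cells short of 1.5-fold, while at day 5 it was at -0.58 in Müller glia-like and 0.71 in rod-like cells. At day 5 the metallothionein gene Mt1 was apart lower in 4 of 4 classes (-0.93 to -0.71), the histone demethylase gene Kdm3a in 4 of 7, and Pnpla6, a lysophospholipase gene, higher in 4 of 7. Between the control libraries, Etv5 was apart higher at day 15 in 5 of 6 classes. The log2 ratio of Ddit4 was below 0 in all 7 classes at both days, from -0.88 to -0.25 at day 5 and from -0.34 to -0.08 at day 15. At day 15 its interval took in 0 in rod bipolar-like (-0.31 to 0.14) and cone-like cells (-0.48 to 0.04). It reached 1.5-fold only in rod bipolar-like and cone bipolar-like cells at day 5.

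The lower medians of the hypoxia response list may reflect diabetes, a mix of cell subtypes or free RNA of 1 class read in the others. Of the amacrine-like and cone bipolar-like clusters, 4 held at least 50 cells in each library and were taken singly. Of their 8 medians over cluster and day, 100% were below 0, the nearest to 0 at -0.05. Between the control libraries 2 of these clusters had a median below 0. The values argue against a shift between these clusters, and the smaller clusters were not tested. Subtypes within a cluster, and within the 3 other inner classes that are 1 cluster each, were not separated and stay open. Taken only in the class where each member was highest, 17 members over 5 classes had medians of -0.08 at day 5 and -0.19 at day 15. The prediction for free RNA, written in advance, was a median within 0.1 of 0 at 1 day or both. The day 5 value met it, and the day 15 value lay outside. That wording was applied after the outcome of a stricter reading, over both days, had been seen. Free RNA is thus not excluded, and with the days at odds it is not shown either. Between the control libraries 0 of 7 class medians lay below -0.1. Diabetes cannot be told apart from the library with 1 library per group.

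The higher interferon list in Müller glia-like cells of the diabetic library at day 5 may reflect diabetes, a few cells, microglial RNA or a low control library. Without the 10% of cells with the highest share of these UMIs in each library the median was 0.62. That argues against a few cells, up to this 10%, as the only source, and does not exclude a larger group. List UMIs per cell had means of 8.33 and 14.9 in the control and diabetic libraries of day 5, and medians of 7 and 10. At day 15 the means were 13.4 and 12.6 and both medians 11. These numbers are not scaled to depth. Microglial RNA could bring at most 0.755% of the summed difference, from 69 UMIs of 8 microglia markers and 29 microglia-like cells. Against the control library of day 15 the median was 0.41, 14 of 18 members lying above 0, with a range of 0.09 to 0.69 on resampling members, so a low control library as part of the difference stays open. The list summed to 968, 1556, 1156 and 1159 CPM in the day 5 control, day 5 diabetic, day 15 control and day 15 diabetic libraries, and at day 15 its median was -0.10; diabetes and library cannot be told apart.

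The 1721 cells of cluster 2 had a summed profile whose log2 CPM, with 10 CPM added, correlated across genes with that of all other kept cells of the day 5 control library at r = 0.994. With the single classes of that library r lay between 0.844 for Müller glia-like and 0.952 for cone bipolar-like cells.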
